A study of Mus musculus with 27 samples.

How the data were processed

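Bulk RNA sequencing was deposited for 27 libraries of mouse bone marrow-derived macrophages, which are macrophages grown from bone marrow precursors with the growth factor CSF-1. The labels give 9 groups of 3 libraries: non-irradiated, FLASH or standard proton irradiation (5 Gy), each followed by 2 days in control medium (M0), LPS at 100 ng/ml (M1) or IL-4 at 20 ng/ml (M2). FLASH irradiation delivers the dose at an ultra-high rate, and the standard arm received the same dose at a conventional rate. Groups were taken from the labels alone.

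Per the submitters' processing notes, the authors quantified the reads with kallisto 0.46.1 and scaled them with edgeR 3.36.0 in R 4.0.5. The same notes name the human build GRCh38 for these mouse samples, so no coordinates are given; 18165 of the 19069 gene symbols were found among mouse GENCODE symbols, and 18844 when RefSeq symbols and synonyms were added. The deposited table holds the signal of each gene in each library as TMM-scaled CPM (read counts scaled to a common library total) on a linear scale, with 19070 entries, of which 1 had no gene symbol and was left out. The column sums ranged from 929399.7 to 1072727.2 and their geometric mean was the nominal CPM total, as TMM scaling gives. No raw counts were used here. The smallest step between values gave back 20.68 M to 25.84 M assigned reads per library. At that step 97.75% of the nonzero values, and 91.97% of those under 20 reads, were whole numbers of reads within 0.01 read. Because not all values were whole, tests made for counts were not used. The scaling factors recovered from the columns ranged from 0.9322 to 1.076. The 10 most abundant genes took 11.26% to 16.94% of a library, mitochondrially encoded genes took 0.47% to 1.53%, and 11577 to 12127 genes per library reached 1 CPM.

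Genes with at least 1 CPM in at least 3 of the 27 libraries were tested (13297 genes). Values were put on the log2(CPM + 0.5) scale, and all fold changes below are on that scale, which understates the change of genes near 0. One linear model with 9 group means was fitted to all 27 libraries in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with an intensity trend and robust moderation of the variances. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. The 18 comparisons were M1 and M2 against M0 without irradiation, each irradiation mode against no irradiation in each state and over the mean of the 3 states, FLASH against standard in each state and over the mean, and the interactions of irradiation with M1 and with M2. In the mean of the states the 3 states have equal weight. The sources do not state whether replicates were separate cultures or animals, so the p-values measure the spread between these libraries only. Replicate number was not in the model.

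A total of 32 gene lists (19 pathways, 3 lists of RNA quality and 10 of cell types) was written from general knowledge, with 6 to 38 tested members, of which 11 entries were matched through a synonym. Each was tested with camera in limma at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation, with fry, and without 5 libraries described below. The lists, the model, the threshold and the rule for naming genes were fixed before the data were examined. By that rule the named genes of a comparison are the 5 highest and 5 lowest called fold changes among genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries compared (for a mean of states, the same direction in all 3 states), without predicted gene models; up to 2 called members per direction of each list, or the member with the smallest p where none was called; and a fixed set of markers whatever their p. In comparisons that called no gene, the genes with the smallest p could be named as well. Other named genes are marked as chosen after the values were seen.

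The agreement of the FLASH and standard changes was measured across genes as a Pearson correlation and a covariance, beside 100 simulated draws of unchanged groups that share the same non-irradiated libraries, and with the non-irradiated libraries split between the arms. The pipeline was tested on simulated data with planted changes of known size. The labels were checked against the data by placing each library on an LPS axis and an IL-4 axis, where 0 is the mean of the non-irradiated M0 libraries and 1 the mean of the non-irradiated M1 or M2 libraries; a library past 0.5 on an axis its label does not name, or short of it on the axis its label names, was counted as at odds with its label. Alternatives tried were another pseudocount, no filter and a stricter filter, median-of-ratios scaling, a variance fit without trend, only the compared groups, a block for replicate number, and leaving out each library in turn. Leaving out the 5 libraries at odds with their labels, and using replicate numbers 2 and 3 only, were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.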

Results

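RNA of mouse bone marrow-derived macrophages was sequenced in 27 libraries, 3 in each of 9 groups. The cells had received FLASH proton irradiation, standard proton irradiation or none, and were then kept in control medium (M0), LPS (M1) or IL-4 (M2). Assigned reads recovered from the table ranged from 20.68 M to 25.84 M per library. Levels below are CPM as mean ± SD of the 3 libraries of a group unless 9 are named, and fold changes are log2 values with limma's adjusted p.

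LPS and IL-4 drive opposed macrophage programs, so the response genes of each were used to compare every library with its label. In 22 libraries the response genes followed the label. The 7 such libraries labelled M1 lay at 0.917 to 1.12 on the LPS axis, the 7 labelled M2 lay at 0.803 to 1.04 on the IL-4 axis, and the 8 labelled M0 lay at or below 0.264 on the LPS axis and 0.0772 on the IL-4 axis. The other 5 libraries, all replicate 1 of irradiated groups, were at odds with their labels. The library labelled FLASH M0 replicate 1 lay at 0.76 on the IL-4 axis, with Arg1 at 655 CPM. The library labelled FLASH M1 replicate 1 lay at -0.24 on the LPS axis and -0.27 on the IL-4 axis. The library labelled FLASH M2 replicate 1 lay at 1.08 on the LPS axis, with Nos2 at 76.9 CPM. The library labelled standard M1 replicate 1 lay at 0.83 on the IL-4 axis, and the library labelled standard M2 replicate 1 lay at 1.16 on the LPS axis. All 5 had Cdkn1a at 478 to 787 CPM and Phlda3 at 85.6 to 156 CPM, within or near the ranges of the 13 remaining irradiated libraries (507 to 858 and 71.7 to 182 CPM) and above the 9 non-irradiated ones (168 to 353 and 16.7 to 46.8 CPM). Every library was kept under its label, and each comparison's count of called genes is also given without these 5. The comparisons without irradiation hold none of the 5, though their spread enters the shared fit.

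**Figure D1:**
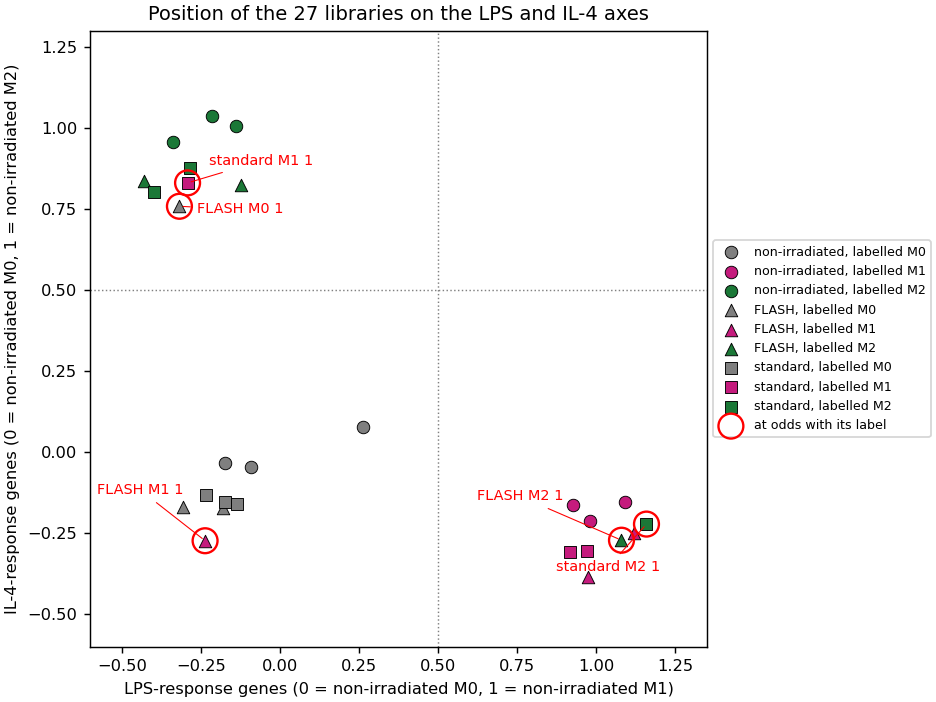
Each point is 1 of the 27 libraries, placed by its LPS-response genes (horizontal axis) and IL-4-response genes (vertical axis), where 0 is the mean of the non-irradiated M0 libraries and 1 that of the non-irradiated M1 or M2 libraries. Color gives the labelled state, shape the irradiation, and red circles the 5 libraries at odds with their labels.

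LPS, a component of the bacterial wall, was compared with control medium in non-irradiated cells to show what the M1 state is in this culture. A total of 1312 genes rose and 1003 fell. With the 5 libraries left out 4610 genes were called, among them all 2315, in the same direction. Nos2, the inducible nitric oxide synthase, rose from 2.20 ± 0.282 to 123 ± 60.3 CPM (log2 5.4, adjusted p = 0.0098). Il23r (a cytokine receptor, log2 5.69), Oasl1 (an antiviral regulator, 5.59), Ccl8 (a chemokine, 5.59) and Ly6a (a surface antigen, 4.21) rose as well, as did the granule protease Gzmb (5.42, from 0.425 ± 0.246 to 38.7 ± 6.59 CPM) and the T cell kinase Lck (2.04). Acsl1 (fatty acid activation, 3.39), the transcription factor Cebpb (2.34), the complement gene C4b (2.91) and the lysosomal protease Ctss (0.97) rose too. Cd163, a scavenger receptor, fell from 20.7 ± 11.3 to 0.997 ± 0.735 CPM (log2 -3.79), with Vsig8 (-4.04), the lipase inhibitor Angptl4 (-3.64), catalase (Cat, -1.78), the receptor ligand Gas6 (-2.18) and the chemokine receptors Cxcr4 (-2.34) and Ccr2 (-2.14). Mt-Cytb, encoded in mitochondria, fell from 912 ± 47.3 to 276 ± 19.1 CPM (adjusted p = 0.0057). Some classic M1 cytokines missed the threshold despite large folds: Il1b changed by log2 3.81 (adjusted p = 0.15), Tnf by 3.11 (0.14) and Il6 by 1.42 (0.28). All 3 were called with the 5 libraries left out (0.000371, 9.03e-08 and 0.0105).

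Among the gene lists, 31 of 35 interferon-stimulated genes rose (35 adjusted over the list alone; median log2 3.53) and 10 of 29 LPS-response genes rose (13 adjusted over the list alone; 3.01). With the 5 libraries left out 24 of the 29 rose. Antigen presentation had 12 genes higher and 4 lower of 24 (13 and 5 adjusted over the list alone), and T and NK cell markers had 3 of 10 higher (5). All 13 mitochondrially encoded genes fell (13; median -1.44), with 4 of 17 neutrophil markers (6), 4 of 38 proliferation genes (1), 5 of 32 DNA repair genes (5) and 4 of 29 TGF-beta and matrix genes (4). Camera called these 9 lists and cholesterol synthesis, where 0 of 24 genes were called by limma (median -0.93, camera adjusted p = 0.0014). None of the 10 held with an estimated correlation, where the adjusted p ranged from 0.34 to 0.75, and no list held in that test without the 5 libraries either. Leaving out 1 library moved the count of called genes to 907 without non-irradiated M0 replicate 1, 1038 without M0 replicate 3, 961 without M1 replicate 2 and 1399 without M1 replicate 3. The genes named with a rise or fall in M1 kept their calls whichever of the 6 libraries was left out.

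IL-4, a cytokine of type 2 immunity, was compared with control medium in the same way. Single genes of alternative activation and of the respiratory chain were higher, and several receptors of macrophages were lower. A total of 656 genes rose and 651 fell, and without the 5 libraries 3455 genes were called, among them all 1307 in the same direction. Retnla, a secreted resistin-like protein, rose from 21.1 ± 7.59 to 3321 ± 496 CPM (log2 7.31, adjusted p = 0.014). Rnase2a (an eosinophil-type ribonuclease, 7.01), Ocstamp (cell fusion, 6.35), the chemokine Ccl24 (4.49), the carbonic anhydrase Car2 (2.88), the glycolytic kinase subunit Pfkp (1.64), Atp5b (ATP synthase, 1.09), Cyc1 (respiratory chain, 1.04) and the class II loading factor H2-DMb1 (1.352) rose. Stab1, a scavenger receptor, fell from 708 ± 192 to 52.4 ± 16.0 CPM (log2 -3.75, adjusted p = 0.0024), with Igfbp4 (-3.73), the chemokine receptor Cx3cr1 (-3.43), the transcription factor Maf (-2.55), the pore-forming Mpeg1 (-2.03), Gas6 (-2.38) and the TGF-beta receptor Tgfbr2 (-1.47). Arg1 changed from 8.09 to 509 ± 303 CPM and missed the threshold (log2 5.65, adjusted p = 0.067), as did Chil3 (4.18, 0.2) and Mrc1 (0.59, 0.8). With the 5 libraries left out Arg1 (1.48e-07) and Chil3 (3.57e-05) were called and Mrc1 was not (0.108). Of the IL-4-response genes 12 of 28 rose and 1 fell (16 and 1 adjusted over the list alone; median 2.66), 11 of 26 oxidative phosphorylation genes rose (21; 0.52), 3 of 30 ribosomal protein genes rose (11) and 4 of 20 immediate early and heat shock genes rose (6). Falls were found for 8 of 17 neutrophil markers (13; median -1.93), 7 of 22 macrophage core genes (8), 5 of 13 complement genes (6) and 4 of 29 TGF-beta and matrix genes (5). Camera called these 8 lists, and also interferon-stimulated genes (1 of 35 lower, 0 over the list alone) and monocyte (1 of 12; 3), B lineage (3 of 9; 5 down, 1 up) and stromal and osteoblast markers (2 of 16; 2). None held with an estimated correlation (adjusted p from 0.098 to 0.87) in the fit of all libraries. With the 5 libraries left out 2 lists held in that test, the IL-4-response genes (21 of 28 higher and 2 lower; adjusted p = 0.000233) and the macrophage core genes (14 of 22 lower and 3 higher; 0.04041). The count fell to 784, 582 and 644 without non-irradiated M0 replicate 1, 2 or 3, and to 621 and 669 without M2 replicate 1 or 2. The genes named here with a rise or fall kept their calls whichever of the 6 libraries was left out.

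Irradiated cells were compared with non-irradiated cells over the mean of the 3 states to show what 5 Gy left behind in macrophages. FLASH raised 433 genes and lowered 594, and standard irradiation raised 447 and lowered 601. Leaving out the 5 libraries gave 1902 and 2382 called genes, of which 915 of the 1027 and 1011 of the 1048 were the same genes in the same direction. Phlda3, a p53-induced inhibitor of Akt signaling, rose from 32.0 ± 12.1 CPM without irradiation to 127 ± 37.2 after FLASH and 134 ± 32.1 after standard irradiation (n = 9 each; log2 2.02 and 2.11, adjusted p = 9.7e-09 and 3.9e-09 by limma). Cdkn1a, the p21 inhibitor of the cell cycle, rose from 250 ± 60.8 to 622 ± 130 and 648 ± 91.5 CPM (log2 1.33 and 1.40). In the order FLASH and standard, Ccng1 rose by 0.71 and 0.78 and Mdm2, which degrades p53, by 0.76 and 0.69. Of the 31 p53 targets 11 and 14 rose and 1 fell in each arm (13 and 16 up, 1 down adjusted over the list alone), and the list held with an estimated correlation (adjusted p = 0.001 and 0.00093). The antioxidant genes under NRF2 held as well (6 and 5 of 26 higher, 8 and 12 over the list alone; adjusted p = 0.036 and 0.029 with an estimated correlation, 0.03584 and 0.06721 without the 5 libraries) and were led by heme oxygenase Hmox1 (1.08 and 1.23) and Gsta3 (0.94 and 1.07). The lysosomal protease Ctsl (1.11 and 1.10), lysozyme Lyz2 (0.75 and 0.75), the amine oxidase Maoa (1.71 and 1.65), the secreted matrix protein Spp1 (1.67 and 1.74) and the costimulatory ligand Cd80 (0.91 and 1.09) rose too. Leaving out 1 library moved neither count past 1.5 times (742 to 1141 and 796 to 1267 genes), and no gene that the rule names for both means and that is given here lost its call in that way.

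Of 24 antigen presentation genes 7 and 8 fell over the mean of the states and 1 rose (8 and 9 down, 1 up adjusted over the list alone), with an adjusted p of 0.066 and 0.089 under an estimated correlation, and of 0.03584 and 0.04884 without the 5 libraries. The MHC class II gene H2-Aa fell from 514 ± 320 CPM to 31.8 ± 20.4 after FLASH and 34.4 ± 30.7 after standard irradiation (n = 9 each; log2 -3.82 and -3.84). H2-Ab1 fell by 3.59 and 3.58 on the log2 scale. Among genes chosen after their values were seen, the invariant chain Cd74 (-3.36 and -3.49) and the class II transactivator Ciita (-2.88 and -2.82) fell, and the class I genes H2-K1, H2-D1, B2m and Tap1 were not called. Of 17 neutrophil markers 13 and 14 fell (14 and 14 over the list alone; median -2.17 and -2.48), such as myeloperoxidase Mpo (-4.06 and -4.39) and the granule protein Ngp (-3.56 and -4.97). Of 9 B lineage markers 8 and 7 fell and 1 rose (8 and 8 down, 1 up over the list alone) and the immunoglobulin chain Ighm was among them (-2.74 and -3.03). Of 6 mast cell and basophil markers 4 and 4 fell (6 and 6), and of 12 monocyte markers 5 and 5 fell (7 and 7; Ccr2 -1.93 and -1.90). Falls were also called for 2 and 3 of 13 dendritic cell markers (6 and 5; Ccr7 -1.89 and -2.06) and 4 and 5 of 12 stem and progenitor markers (6 and 7 down, 1 up in each). These 6 lists held with an estimated correlation in both arms (adjusted p from 0.001 to 0.021), and 5 of them did without the 5 libraries, where the mast cell and basophil markers did not (0.06504 and 0.09998). T and NK cell markers (5 and 3 of 10 lower, 8 and 4 over the list alone; Gzmb -2.89 and -2.36) and erythroid and megakaryocyte markers (3 and 3 of 10 lower, 3 and 3 over the list alone; Itga2b -3.11 and -3.13) held for FLASH (0.04 and 0.036) and not for standard irradiation (0.27 and 0.13), and for neither arm without the 5 libraries.

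**Figure D2:**
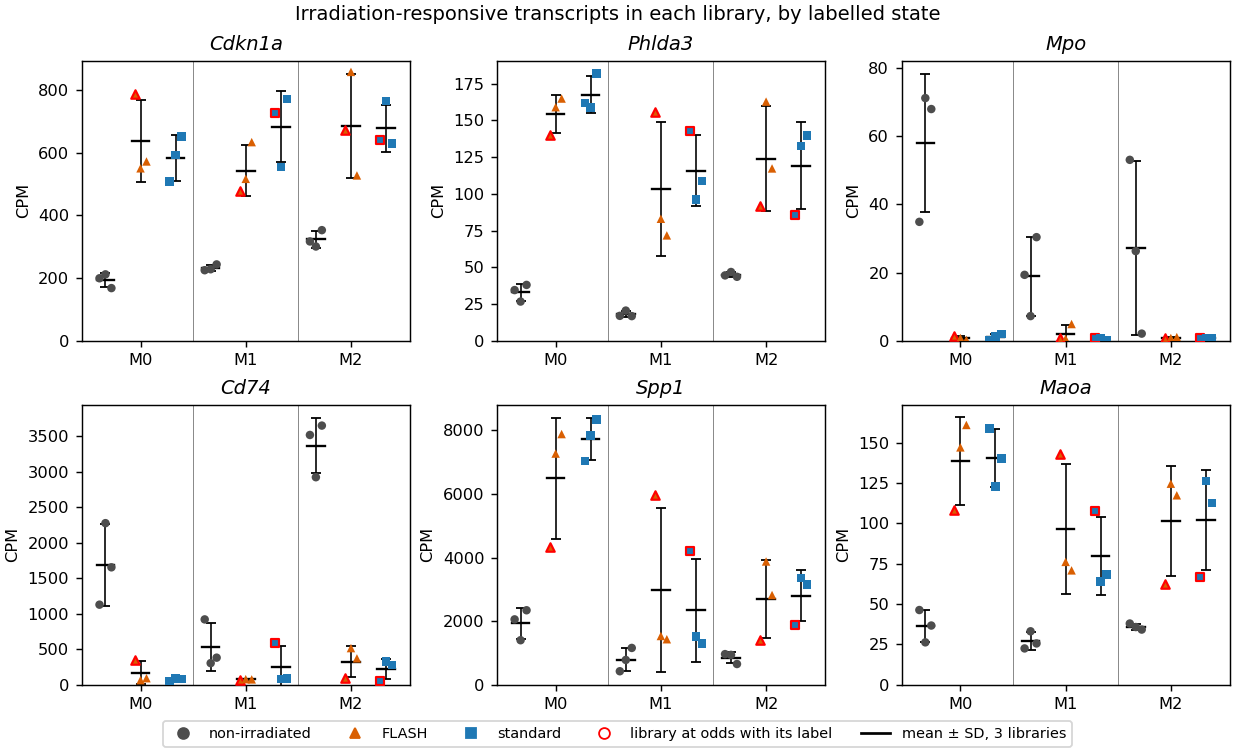
CPM of 6 transcripts in each library (points) by labelled state and irradiation, with mean ± SD of 3 libraries; red outlines are the 5 libraries at odds with their labels. Cdkn1a and Phlda3 were above every non-irradiated library in all 18 irradiated ones.

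The other lists did not hold with an estimated correlation over the mean of the states in the fit of all libraries. Phagocytosis and lysosome genes were called by camera (5 and 6 of 33 higher, 9 and 6 up and 1 down over the list alone), without holding under an estimated correlation (adjusted p = 0.098 and 0.15). The same was true of the lipid oxidation enzymes (2 of 14 lower in each arm and 2 over the list alone; 0.066 and 0.089), of which Alox12 (-2.44 and -2.79) and Mpo were the called genes, and of proliferation genes (0 of 38 called by limma; median -0.40 and -0.38; 0.69 and 0.75), where Mki67 changed by -0.65 and -0.72 without a call. Stromal and osteoblast markers (1 and 2 of 16 lower, 1 and 3 over the list alone), mitochondrially encoded genes (2 and 1 of 13 higher, 5 and 1) and ribosomal protein genes (5 and 0 of 30 lower, 14 and 0) were called by camera too and did not hold (0.17 to 0.72). Interferon-stimulated genes, chemokines and receptors, and glycolysis and hypoxia genes were called by camera for FLASH alone (camera adjusted p = 0.017, 0.042 and 0.02) and did not hold either (0.74, 0.44 and 0.21). In both arms camera called neither the LPS-response (0.75 and 0.66) nor the IL-4-response genes (0.071 and 0.15; with the 5 libraries left out these were lower with an estimated correlation, 0.02234 and 0.04206), nor DNA repair (0.24 and 0.19), senescence (0.38 and 0.69), PPARgamma and lipid handling (0.38 and 0.29), cholesterol synthesis (0.38 and 0.19), complement (0.059 and 0.15), oxidative phosphorylation (0.38 and 0.19), TGF-beta and matrix (0.63 and 0.89), macrophage core (0.38 and 0.45), immediate early (0.87 and 0.49) or osteoclast genes (0.63 and 0.83). Within these, Vegfa fell (-1.66 and -1.35), C1qb fell (-0.83 and -0.82) and H2afx fell (-0.75 and -0.56), and Pparg was not called (-0.37 and -0.43, adjusted p = 0.61 and 0.53). The IL-4-response gene Ccl24 was called for FLASH (-1.22, limma adjusted p = 0.042) and not for standard irradiation (-1.1, 0.066). Without the 5 libraries 13 and 11 of the 28 IL-4-response genes fell, and 0 and 1 rose.

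**Figure D3:**
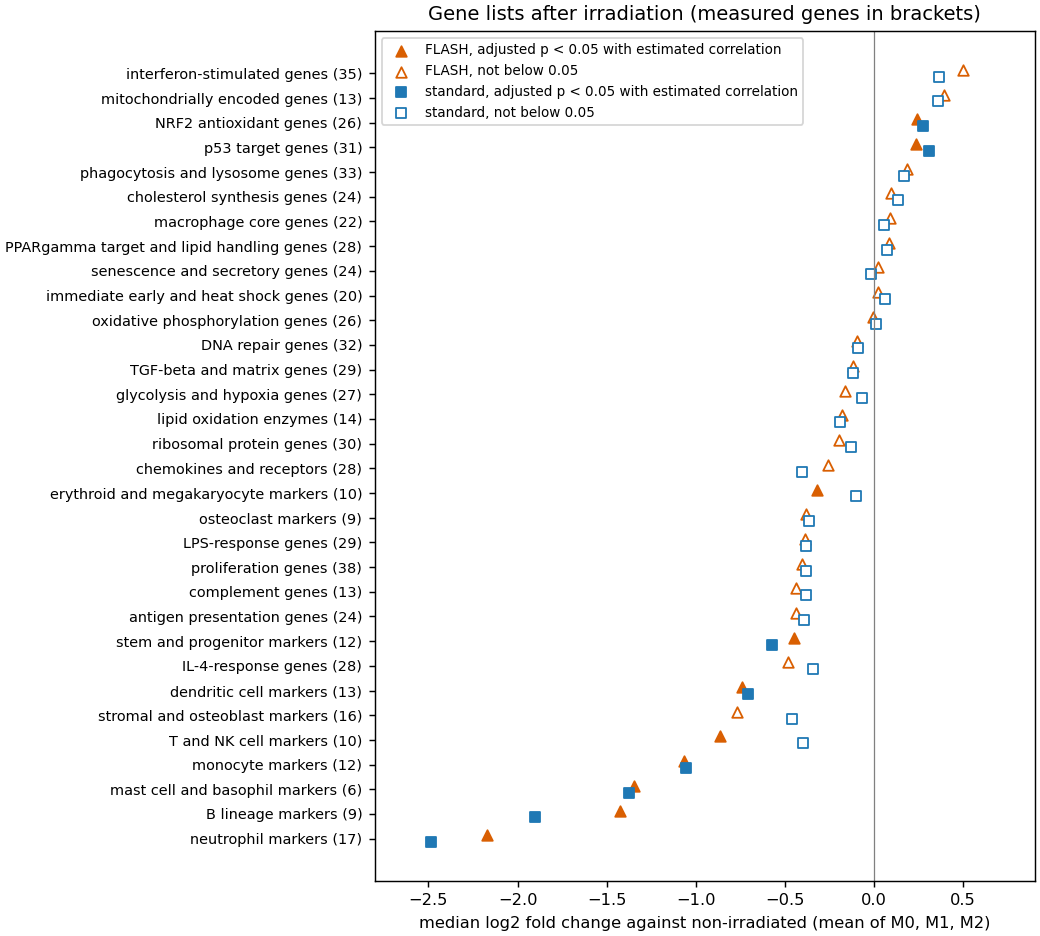
Median log2 fold change of the tested genes of each list against non-irradiated cells, mean of the 3 states, for FLASH (triangles) and standard irradiation (squares); filled symbols have an adjusted p below 0.05 with an estimated correlation. Neutrophil and B lineage markers had the lowest medians in both arms, and p53 targets and NRF2 genes were the filled lists on the positive side.

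In control medium FLASH raised 65 genes and lowered 216, and standard irradiation raised 90 and lowered 179. A fit of the compared groups alone called 237 and 737. Without the library labelled FLASH M0 replicate 1 and the other 4 libraries at odds with their labels, 704 and 978 genes were called, of which 242 of the 281 and all 269 were the same genes in the same direction. Phlda3 rose from 33.0 ± 5.8 to 155 ± 13 and 168 ± 12.6 CPM, and Cdkn1a from 193 ± 22.6 to 636 ± 131 and 584 ± 72.7 CPM (limma adjusted p = 1.3e-05 and 3.8e-05). Maoa rose by 1.94 and 1.97, the serotonin receptor Htr2b by 2.12 and 1.92 and Hmox1 by 1.08 and 1.3. Mpo fell from 58.0 ± 20.1 to 0.774 ± 0.537 and 1.11 ± 0.932 CPM, Ngp from 214 ± 69.0 to 9.94 ± 13.2 and 2.41 ± 1.76 CPM, and H2-Aa from 606 ± 206 to 28.1 ± 17.0 and 16.8 ± 5.99 CPM. Of the neutrophil markers 13 and 13 of 17 fell (14 and 15 over the list alone; median -3.02 and -3.89), of the B lineage markers 6 and 5 of 9 (6 and 6), of the monocyte markers 3 and 2 of 12 (4 and 7) and of the dendritic cell markers 2 and 2 of 13 (4 and 3). These lists held with an estimated correlation, as did p53 targets (5 and 4 of 31 higher, 1 and 1 lower; 6 and 7 up, 2 and 1 down over the list alone) and lipid oxidation enzymes (2 and 2 of 14 lower, 3 and 2 over the list alone; adjusted p = 0.022 and 0.03 with an estimated correlation). In that test without the 5 libraries all held but the lipid oxidation enzymes after standard irradiation (0.05748). Antigen presentation (7 and 7 of 24 lower) did not (0.15 and 0.14). Single libraries moved the FLASH count to 177, 179 and 148 without FLASH M0 replicate 1, 2 or 3 and to 180 and 140 without non-irradiated M0 replicate 1 or 3. They moved the standard count to 132 and 152 without standard M0 replicate 1 or 3 and to 169, 166 and 146 without non-irradiated M0 replicate 1, 2 or 3.

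Under LPS FLASH raised 97 genes and lowered 239, and standard irradiation raised 131 and lowered 215. The fit of the compared groups alone called fewer, 90 and 54. Without the 5 libraries, which include the libraries labelled FLASH M1 replicate 1 and standard M1 replicate 1, 644 and 734 genes were called, of which 277 of the 336 and 294 of the 346 were the same genes in the same direction. Phlda3 rose from 18 ± 2.13 to 104 ± 45.6 and 116 ± 24.2 CPM, and Cdkn1a by 1.21 and 1.54. Gzmb fell from 38.7 ± 6.59 to 0.269 ± 0.256 and 0.747 ± 0.0993 CPM (limma adjusted p = 6.2e-08 and 3.2e-07). Tusc3 fell from 17.8 ± 6.83 to 0.015 ± 0.0221 and 0.185 ± 0.32 CPM, the angiogenic factor Vegfa by 2.02 and 1.94 on the log2 scale, the platelet chemokine Ppbp by 4.29 and 4.87, and the complement gene C4b by 2.21 and 2.54. In the FLASH arm the granzyme Gzmc fell by 4.16 and the cytokine receptor chain Il2rb by 4.48. The class II genes H2-Aa (-2.83) and H2-Ab1 (-2.54) were called for FLASH, but not without the library labelled FLASH M1 replicate 1 (adjusted p = 0.0588 and 0.1127) or without non-irradiated M1 replicate 1 (0.0777 and 0.117). The p53 targets held with an estimated correlation (6 and 6 of 31 higher, 8 and 11 over the list alone), as did B lineage (5 and 5 of 9 lower, 1 and 1 higher), mast cell and basophil (3 and 2 of 6 lower) and monocyte markers (2 and 2 of 12 lower). T and NK cell markers (5 of 10 lower, 8 over the list alone) and antigen presentation (3 of 24 lower, 10) held for FLASH, at adjusted p = 0.023 and 0.049, and neutrophil markers held for standard irradiation (7 of 17 lower, 13; 0.043). Of all these, the p53 targets in both arms (0.04941 and 0.04977) and the B lineage and the T and NK cell markers for FLASH (0.04941 and 0.04941) held in that test without the 5 libraries, and the others did not (0.06913 to 0.1219). Interferon-stimulated genes had medians of -1.39 and -1.46 with 0 and 0 of 35 called by limma and an adjusted p of 0.57 and 0.52 with an estimated correlation; without the 5 libraries the medians were -0.44 and -0.62. The FLASH count moved to 158 without the library labelled FLASH M1 replicate 1 and to 151, 169 and 183 without non-irradiated M1 replicate 1, 2 or 3. The standard count moved to 132 without the library labelled standard M1 replicate 1, to 199 without standard M1 replicate 3, and to 133, 171 and 170 without non-irradiated M1 replicate 1, 2 or 3.

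Under IL-4 FLASH raised 58 genes and lowered 88, and standard irradiation raised 74 and lowered 106. The fit of the compared groups alone, with 6 libraries behind the spread, called almost none, 0 genes by limma for FLASH and 2 for standard irradiation. Without the 5 libraries, which include the libraries labelled FLASH M2 replicate 1 and standard M2 replicate 1, 436 and 449 genes were called, of which 126 of the 146 and 151 of the 180 were the same genes in the same direction. Phlda3 rose from 44.9 ± 1.67 to 124 ± 35.9 and 119 ± 29.4 CPM, Cdkn1a by 1.06 and 1.06, Ccng1 by 0.68 and 0.76 and Cd80 by 1.41 and 1.55. H2-Ab1 fell from 990 ± 189 to 63.8 ± 23.4 and 47.8 ± 19.4 CPM (limma adjusted p = 0.0024 and 0.00054), H2-Aa by 4.13 and 4.58 on the log2 scale and Gzmb by 2.66 and 2.48. The p53 targets held with an estimated correlation (3 and 5 of 31 higher, 10 and 10 over the list alone; adjusted p = 0.014 and 0.0079), but not without the 5 libraries (0.09612 and 0.07499). B lineage markers (2 and 3 of 9 lower, 6 and 6) held for standard irradiation (0.028; 0.1768 without the 5 libraries) and not for FLASH (0.053). Antigen presentation genes (7 and 7 of 24 lower, 1 and 1 higher) had a positive median of 0.18 and 0.22, while camera placed the list lower (adjusted p = 0.031 and 0.027; 0.52 and 0.54 with an estimated correlation); the median was negative without the 5 libraries (-0.15 and -0.24). Interferon-stimulated genes had medians of 2.21 and 2.07 with 3 and 2 of 35 called (11 and 21 over the list alone) and did not hold with an estimated correlation (0.35 and 0.4); without the 5 libraries the medians were 0.95 and 1.02. Of the 28 IL-4-response genes 4 and 5 fell and 0 rose without the 5 libraries (adjusted p = 0.104 and 0.1768 with an estimated correlation). By library, among genes chosen after their values were seen, Retnla ran from 3007 to 3892 CPM and Mgl2 from 543 to 769 without irradiation. In replicates 2 and 3 of both irradiated arms they ran from 1306 to 1497 and 218 to 257. Arg1 (161 to 713, then 631 to 1057) and Chil3 (3716 to 5771, then 5814 to 6483) were not lower. The FLASH count moved to 58 and 73 without FLASH M2 replicate 1 or 3 and to 39 and 78 without non-irradiated M2 replicate 1 or 2. The standard count moved to 75 and 88 without standard M2 replicate 1 or 3 and to 54 and 101 without non-irradiated M2 replicate 1 or 2.

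FLASH was compared with standard irradiation at the same dose to ask whether dose rate changes the transcripts of macrophages. No gene differed by limma in M0, M1, M2 or the mean of the states. At an unadjusted p under 0.05 there were 397, 382, 227 and 393 genes, and the smallest adjusted p was 0.8939, 0.8251, 0.6669 and 0.2464. Without the 5 libraries the counts were 0 as well (587, 624, 612 and 1071 genes at an unadjusted p under 0.05; smallest adjusted p 0.6948, 0.05946, 0.1273 and 0.1308). Over the mean of the states, leaving out 1 library gave 0 to 11 genes, 11 without the library labelled standard M2 replicate 1 and 3 without FLASH M0 replicate 2. Among genes within the naming rule's limits on level, direction and name, those with the smallest p over the mean were Plet1 (1.51), Gkn1 (2.12) and Dpcr1 (1.97) on the higher side of FLASH and Reg4 (-1.08), Akirin2 (-0.36) and Srp54b (-0.37) on the lower. The p53 genes had narrow intervals: the FLASH minus standard difference was -0.07 for Cdkn1a (95% interval -0.29 to 0.14) and -0.10 for Phlda3 (-0.39 to 0.20). The interval for Pparg was -0.70 to 0.80 and that for H2-Ab1 -0.70 to 0.67; Phlda3, H2-Ab1, S100a9 and Gzmb were chosen here after their values were seen. Across all genes the median half-width of the interval was 0.32, and 92% of genes had an interval within -1 to 1. In simulated data this comparison recovered 51.6% of planted changes of log2 0.5 and 87.6% of changes of log2 1. The simulated spread was that of the non-irradiated libraries, none of which is at odds with its label. Recovery among the irradiated libraries, which include the 5, may therefore be lower. Camera called neutrophil markers higher over the mean (median 0.35, adjusted p = 2.9e-08; 0 members called, 3 over the list alone) and T and NK cell markers lower (-0.45, 2.3e-06; 0 called, 2 over the list alone). Without the 5 libraries camera no longer called the neutrophil markers (median 0.1924, adjusted p = 0.1237) and still called the T and NK cell markers (-0.415, 0.00418). Neither list held with an estimated correlation (0.27 and 0.27). In single states camera placed IL-4-response genes higher with FLASH in M0 (median 0.72) and lower in M1 (-0.78), where libraries at odds with their labels fall into the groups, and these did not hold either (0.95 and 0.94). Among the single genes of these lists, S100a9 differed by 1.70 (adjusted p = 0.771), Cd177 by 1.41 (0.246) and Gzmb by -0.53 (1). Lipid oxidation enzymes and PPARgamma targets had medians of -0.01 and -0.01 and were not called (0.84 and 0.84).

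**Figure D4:**
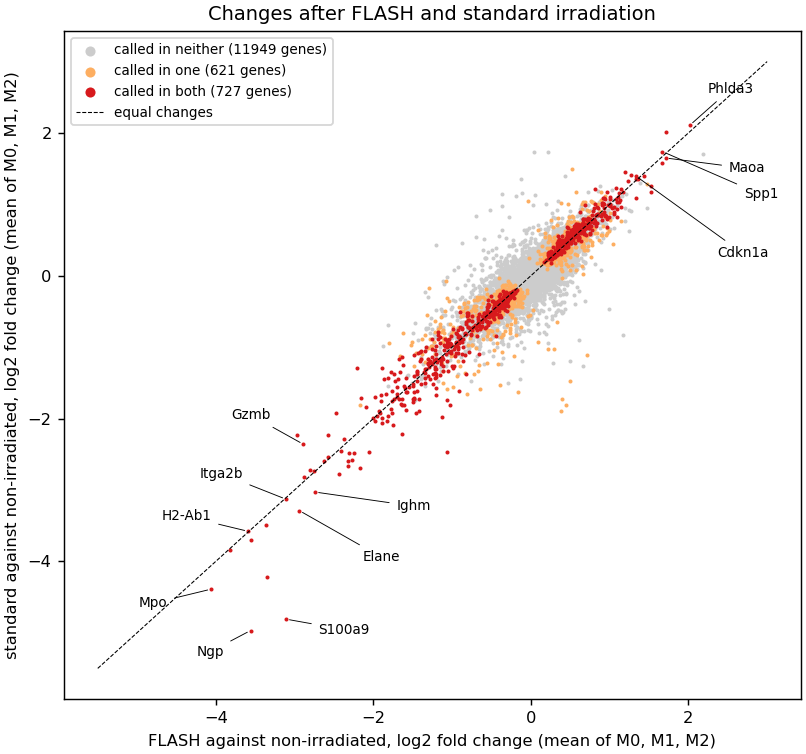
Each point is 1 of 13297 genes, with its log2 fold change after FLASH (horizontal axis) and after standard irradiation (vertical axis) against non-irradiated cells, mean of the 3 states; the dashed line marks equal changes. Genes called in both arms lay on the same side of 0 in both.

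**Figure D5:**
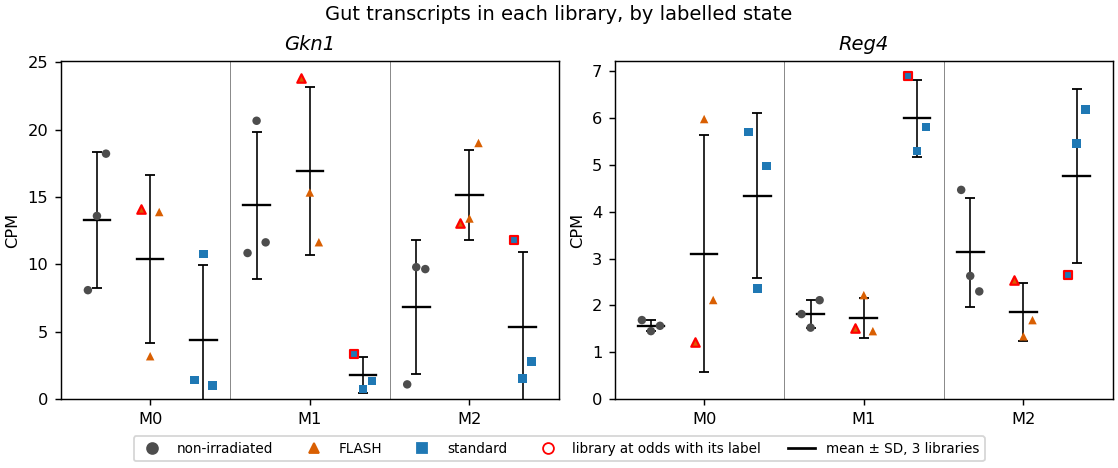
CPM of the gut transcripts Gkn1 and Reg4 in each library (points), by labelled state and irradiation, with mean ± SD of 3 libraries; red outlines are the 5 libraries at odds with their labels. Gkn1 ranged from 0.744 to 23.8 CPM over the 27 libraries.

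The FLASH and standard changes were set against each other across genes, which are not independent replicates. Over the mean of the states the correlation was 0.881 and the covariance 0.131, whereas unchanged groups that share the same controls gave 0.497 and 0.0169 on average over 100 simulated draws. The correlation in M0, M1 and M2 was 0.821, 0.842 and 0.863, against 0.5, 0.499 and 0.5 simulated. In M1 and M2 both arms hold a replicate 1 library at odds with its label. On the LPS axis these lay at -0.24 (FLASH) and -0.29 (standard) in M1, and at 1.08 and 1.16 in M2. On that axis they move both arms the same way from the controls, and the simulated groups hold no such libraries. On the IL-4 axis the replicate 1 libraries in M1 lay apart, at -0.27 (FLASH) and 0.83 (standard). Without the 5 libraries the correlation was lower in M1, in M2 and over the mean, as given below. With the non-irradiated libraries divided between the arms, 6 divisions gave correlations of 0.583 to 0.768 and covariances of 0.105 to 0.126. Of the called genes 304 were higher in both arms, where independent lists would share 14.6, and 423 were lower in both, where 26.9 would be shared. No gene was called in opposite directions. The shared controls raise such overlaps by themselves, and the covariance above the simulated one, 0.114, is the part they do not account for. Libraries at odds with their labels in both arms can add to that part.

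Whether irradiation acts differently under LPS or IL-4 than in control medium was tested as an interaction. For LPS 6 genes were higher and 10 lower with FLASH and 4 and 8 with standard irradiation, and 0 genes were called by limma for IL-4 with either mode (791 and 661 at an unadjusted p under 0.05). For LPS 51 and 51 genes were called without the 5 libraries, 11 and 10 of them the same genes in the same direction, and for IL-4 0 and 3 (smallest adjusted p 0.05695 for FLASH). The counts for LPS depended on the settings: 2 and 6 genes were called with the compared groups alone, 40 and 22 with a pseudocount of 2, and 40 and 25 with no filter. Gzmb (-5.4 and -5.34) and Gzmc (-3.98 and -3.61), granule proteases of killer cells, rose with LPS in non-irradiated cells (5.42 and 3.87) and stayed below 1 CPM in every irradiated group. Tle1, a transcriptional corepressor, had interactions of 1.55 and 1.51, since LPS lowered it from 25.0 ± 2.13 to 5.95 ± 0.978 CPM without irradiation and irradiated M1 groups had 13.7 ± 2.5 and 12.3 ± 1.92 CPM. These 3 kept their calls whichever library was left out. Txk, Tom1l2, Serpina3b and Vsig8, picked because both modes shared them, were called as well. The p53 genes Cdkn1a and Phlda3 had no interaction called in either mode (adjusted p from 0.55 to 0.97). No list held with an estimated correlation for FLASH or for LPS, and monocyte markers did for IL-4 after standard irradiation (median 1.45, adjusted p = 0.047), but not without the 5 libraries (0.2122). The FLASH count for LPS ran from 5 to 19 as single libraries were left out, with 6 and 7 genes without FLASH M0 replicate 1 or 3, 6 without FLASH M1 replicate 3, 6, 9 and 6 without non-irradiated M0 replicate 1, 2 or 3, and 5 and 7 without non-irradiated M1 replicate 2 or 3. The standard count ran from 5 to 8, with 5, 7 and 7 without standard M0 replicate 1, 2 or 3, 5, 7 and 6 without standard M1 replicate 1, 2 or 3, 6 and 6 without non-irradiated M0 replicate 1 or 3, and 6 and 5 without non-irradiated M1 replicate 2 or 3.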

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

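The interactions were planned, and the tests on other splits of the samples in this part were chosen only after the result was seen. Each gene below was marked because its response to irradiation under LPS differed from that in control medium by limma's test of the interaction.

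With FLASH, the interaction (M1 minus M0, log2) was 3.61 for Vsig8, an immunoglobulin-type surface gene, 2.88 for Pxylp1, 1.55 for the corepressor Tle1, 1.49 for the histone gene H2afx and 1.36 for the cell cycle partner Tfdp2. It was -7.85 for Tusc3, -5.403 for Gzmb, -3.98 for Gzmc, -1.90 for the pseudogene Bambi-ps1 and -1.18 for the B cell surface protein Cd22. With standard irradiation it was 3.79 for Vsig8, 2.59 for the fatty acid hydroxylase Cyp4f18, 1.51 for Tle1, -5.34 for Gzmb, -3.61 for Gzmc, -1.89 and -1.56 for the phosphodiesterases Pde7b and Pde8b, and -0.92 for Tom1l2. Tusc3, Gzmb, Gzmc and Tle1 kept these calls whichever library was left out. Each of the others lost its call without at least 5 of the 12 libraries of its comparison, among them non-irradiated M0 replicate 1 (adjusted p from 0.0884 to 0.142) and non-irradiated M1 replicate 2 (0.0761 to 0.154). Without the 5 libraries at odds with their labels, Pxylp1 (0.0575), Tfdp2 (0.087) and Bambi-ps1 (0.0522) were no longer called.

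Gzmb and Gzmc shared a shape in both modes: LPS raised them in non-irradiated cells, and their means in the irradiated M1 groups were below 1 CPM. Tusc3 was near 0 in every non-irradiated M0 and M2 library and reached 17.8 ± 6.83 CPM in non-irradiated M1, and its FLASH M0 level of 5.64 ± 5.5 CPM varied between libraries as widely as its mean. Other splits of the samples were fitted to see how often they call as many genes. For FLASH 11 of 100 splits called at least the 16 genes found, and for standard irradiation 12 of 100 called at least the 12 found. Chance was not excluded for either count, but the shares do not decide it. Splits that exchange labels unevenly between the 2 states carry irradiation changes into the contrast. The highest other splits called 695 and 783 genes, many times the real counts. Each exchanged the 2 irradiation labels for all 6 libraries in M0 and for 0 in M1, which tests the sum of the irradiation changes in the 2 states, so the structure it points to is irradiation itself. For IL-4 the real counts were 0 and 0, which all 100 of 100 splits reach, with 727 and 774 genes in the highest, which exchanged all 6 labels in M0 and 0 in M2. No biological explanation was tested for the interactions.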

How the results depend on the processing

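Leaving out the 5 libraries at odds with their labels, and using replicate numbers 2 and 3 only, were chosen after the data were seen, and the other alternatives were planned. The planned fit of edgeR on recovered reads was not run, because the recovered values were not all whole numbers of reads.

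Of 486 calls of named genes, none reversed under any alternative. With median-of-ratios scaling (size factors 0.9805 to 1.019) 1 of 481 was lost and every count of genes stayed within 1.5 times its value. Another pseudocount lost 6, the fit without trend 15, the stricter filter 16 of 433, leaving out the 5 libraries 21, no filter 34, replicate numbers 2 and 3 only 108, the replicate block 121 and the fit of compared groups alone 141. As single libraries were left out, 262 kept the call in every case and 224 lost it in at least 1.

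The counts were higher without the 5 libraries: 4610 for M1 and 3455 for M2 without irradiation; 704, 644, 436 and 1902 for FLASH in M0, M1, M2 and their mean; 978, 734, 449 and 2382 for standard irradiation; 51 and 51 for the LPS interactions; and 3 for the IL-4 interaction of standard irradiation (Amica1, Dapp1 and Ocstamp, chosen after their values were seen). The comparisons without irradiation hold none of the 5, so their gain comes from the smaller spread in the shared fit. The correlation of the FLASH and standard changes was 0.816 in M0 without the 5, and fell to 0.75 in M1, 0.675 in M2 and 0.805 over the mean; the cause was not tested, and 5 groups have 2 libraries there. With replicate numbers 2 and 3 only, 2434 genes were called for M2 without irradiation, 448 for FLASH in M0, 118 for standard irradiation in M2 and 3 for its IL-4 interaction; the cause was not tested.

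A fit of the compared groups only, with fewer libraries behind the spread, called 3897 genes for M1 and 737 for standard irradiation in M0, where the doubted libraries drop out, and 90 for FLASH in M1, 54 for standard irradiation in M1, 0 for FLASH in M2 (by limma; 1811 at an unadjusted p under 0.05 in the fit of all groups), 2 for standard irradiation in M2, and 2 and 6 for the LPS interactions. The stricter filter of 5 CPM, which tested 10523 genes, called 161 for FLASH in M0, 223 for FLASH in M1 and 4 for the LPS interaction of standard irradiation. A pseudocount of 2 called 40 and 22 genes for the LPS interactions and 5 and 7 for those of IL-4. No filter gave 40, 25, 7 and 10 for the same, and 2 genes for FLASH against standard in M2. No trend gave 26 for the LPS interaction of FLASH, 3 for the IL-4 interaction of standard irradiation and 1 for FLASH against standard in M2. The cause was not tested for these.

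A block for replicate number called 171 for standard irradiation in M0, 192 and 191 for FLASH and standard irradiation in M1, 75 and 95 in M2, and 5 and 5 for the LPS interactions. Of 108 pairs of libraries with the same number in different groups, 9 had a correlation over 0.1 (from -0.8517 to 0.7833), and 2 of 27 libraries correlated best with their own number. With the 5 libraries left out 2 of 78 pairs were over 0.1 (from -0.2966 to 0.143), and 0 of 22 libraries correlated best with their own number. FLASH and standard libraries of the same number correlated at 0.36 to 0.595 in M1 and 0.4638 to 0.7833 in M2, where both replicates 1 are at odds with their labels, and at -0.01582 to 0.143 without the 5. These last values rest on groups of 2 libraries, whose deviations mirror each other, so they are a weak check. By these correlations the numbers did not pair the libraries across all groups. Libraries of the same number share a code in the titles whose meaning is not stated. The closest pairs of all were replicate 2 of FLASH and standard irradiation in M0 and in M1. Replicates 2 and 3 of the same arms in M2 were close as well, with pairs of unlike numbers among them. A shared origin of FLASH and standard libraries of the same state and number therefore stays open. FLASH against standard had 0 genes called with the block, as without it.

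Leaving out each library in turn gave 907 to 2004 genes for M1 and 582 to 958 for M2 without irradiation; 140 to 243, 151 to 288, 39 to 120 and 742 to 1141 for FLASH in M0, M1, M2 and the mean; 132 to 185, 132 to 289, 54 to 191 and 796 to 1267 for standard irradiation. For FLASH against standard it gave 0 to 0 in each state and 0 to 11 over the mean, 11 without the library labelled standard M2 replicate 1. The LPS interactions ran from 5 to 19 and 5 to 8, and the IL-4 interactions from 0 to 2 and 0 to 3. These fits have fewer libraries per group, which lowers the counts by itself.

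Of 576 list tests camera called 225; 48 of these held with an estimated correlation, and fry called 129, of which 119 were shared. The replicate block gave 227 and leaving out the 5 libraries 221, of which 180 were shared, with 36 under an estimated correlation. Depth did not limit the well expressed genes, but a gene near 1 CPM rests on few reads (about 20 or more), so its folds depend on the pseudocount.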

Other observations

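The tests of the 3 patterns weighed in this part, and those on other splits of the samples, were chosen only after the result was seen.

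Some genes that no comparison above discusses also changed in the irradiated cultures, and no test assigned them to a cell type. Over the mean of the states Timp3, an inhibitor of matrix proteases, fell by 2.57 after FLASH and 2.23 after standard irradiation on the log2 scale. The kinase Dmpk rose by 1.72 and 2.02. Vsig4, a complement receptor of resident macrophages, rose by 1.66 and 1.58, and for standard irradiation it lost its call without non-irradiated M0 replicate 3 (adjusted p = 0.0543) or M1 replicate 1 (0.0526).

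In non-irradiated cultures LPS raised 6 single genes known from NK and T cells, chosen after their values were seen: Gzmb by 5.42, Gzmc by 3.87, the receptor chain Il2rb by 3.04, interferon gamma (Ifng) by 2.26, Lck by 2.04 and the kinase Txk by 1.98. The fixed list of T and NK cell markers had 3 of 10 higher with LPS and did not hold with an estimated correlation (adjusted p = 0.53).

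The 5 libraries at odds with their labels are the first pattern weighed. In each case another of the 5 in the same arm holds the state the label names: the number of libraries with such a partner was 5 of 5. Irradiation overriding the LPS or IL-4 response would show in replicates 2 and 3 as well, but 0 of the 10 other libraries in the 5 groups were at odds with their labels. A mixture of cultures should leave part of the labelled response, and the highest position of the 4 libraries labelled M1 or M2 on their own axis was -0.2214. Labels exchanged among irradiated libraries of replicate 1 are therefore a candidate explanation, and where an exchange could have happened stays open.

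The fall of transcripts of other blood cell types after irradiation is the second. Fewer other blood cells in the irradiated cultures stay a candidate for it. All 8 of the 8 marker lists had a negative median in both arms. Without the 5 libraries these medians ran from -2.315 to -0.3951 after FLASH and from -2.508 to -0.04849 after standard irradiation. Their sign largely restates the pattern, so it cannot tell fewer cells from lower expression within cells. For the neutrophil markers, a general fall of transcripts at their level was argued against by 1000 random lists matched on level, whose lowest median was -0.376. The 5 libraries at odds with their labels were argued against as their source too. Without them the neutrophil median was still -2.315 in the arm nearer to 0. Random lists were not drawn for the other marker lists. Before irradiation Mpo was at 34.7 ± 24.8 and Cd74 at 1859 ± 1290 CPM over 9 libraries. Macrophages also express some monocyte and dendritic cell markers and MHC class II, so lower expression within macrophages stays open for those, and no cell counts were used here.

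The third is a set of transcripts known from gut tissue, noticed after the values were seen among the genes with the smallest p for FLASH against standard irradiation. None was called with all libraries, genes not known from the gut stood among them, and no fixed gut list was tested for a difference between the arms. Without the library labelled standard M2 replicate 1, 11 genes were called, 8 higher and 3 lower with FLASH, among them Gkn1 (14.2 ± 5.56 CPM with FLASH, 3.87 ± 4.29 with standard and 11.5 ± 5.70 without irradiation, n = 9 each) and Reg4 (2.23 ± 1.47, 5.03 ± 1.53 and 2.17 ± 0.945). Gut genes outside the 11 went both ways. Gkn2 (13.5 ± 5.36 with FLASH and 3.65 ± 4.55 with standard), Tff1 (18.4 ± 7.42 and 5.47 ± 6.53) and Krt20 (7.825 ± 2.04 and 4.78 ± 1.34) had higher means with FLASH. Cyp2c55 had a lower mean (4.60 ± 5.43 and 12.6 ± 7.14). Lgals4 (34.2 ± 4.11 with FLASH and 31.9 ± 3.58 with standard) and Muc2 (8.33 ± 2.01 and 8.29 ± 1.16) were alike in the arms. The mean of the 8 genes ranged over 2.186 (log2) within the 9 non-irradiated libraries, beside 1.488 between the arms, so they also vary without irradiation. For Gkn1 the low end was M2 replicate 1 alone, at 1.105 CPM, beside 8.09 to 20.7 CPM in the other non-irradiated libraries. A range of single libraries over 3 states readily exceeds a difference of means. The comparison therefore cannot decide whether irradiation mode adds to their variation. Most standard libraries had low Gkn1 with high Reg4, and most FLASH libraries the reverse. FLASH M0 replicate 2 (3.19 and 5.97 CPM) and non-irradiated M2 replicate 1 (1.105 and 4.46) lay with the former. Standard M0 replicate 2 (10.8 and 2.37) and the library labelled standard M2 replicate 1 (11.8 and 2.65) lay with the latter. Gkn1 and Reg4 thus did not divide the libraries by irradiation mode alone. Reads or RNA of gut tissue from outside the cultures may add to it: in a list of intestine genes, 15 of 21 measured, the libraries moved together around their group means (mean correlation 0.2391, against at most 0.2177 in 1000 random lists). A list of brain genes, 15 of 15 measured, gave 0.4581, so such a correlation is not specific to the gut, and 1 of 9 stomach genes was measured, so the source stays open.

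For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real counts of 2315 and 1307 genes for M1 and M2 without irradiation stood beside 2 and 1 genes in the highest other split. For FLASH in M0, M1 and M2 they were 281, 336 and 146 beside 3, 1 and 0, and for standard irradiation 269, 346 and 180 beside 1, 0 and 1. For FLASH against standard they were 0, 0 and 0 beside 1, 0 and 0, which all 10 of 10 splits reach. For the means of the states 100 of 4000 possible splits were fitted, the real one among them. In 1 of 100 splits, the real one, 1027 genes were reached with FLASH, and 1 of 100 reached 1048 with standard irradiation. Chance is thus unlikely for these counts if the libraries are independent, which the sources do not state. The highest other splits called 590 and 849 genes. For FLASH against standard over the mean all 100 of 100 splits reached the real count of 0, as any split must. The highest called 1681 genes, which points to a structure of the samples apart from irradiation mode. The compared groups hold the 5 libraries at odds with their labels, and whether that split follows them was not tested.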
